A study of Homo sapiens with 6 samples.

How the data were processed

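Total RNA of 6 samples was hybridised to Illumina HumanHT-12 version 4 bead arrays, 1 array per sample and 1 colour, per the labels. Samples were grouped by their labels into 6 groups of 1. The authors deposited a table of non-normalized signal intensity for 47322 probes, with positive values whose medians differed between arrays, which holds no background subtraction as the values show. The same deposited table gives a detection p-value for each probe and array, per the file headers, in steps that imply 769 negative control beads. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. The authors also deposited processed intensity values, which the values show to be on the linear scale with equal quantiles on all 6 arrays, a median of 104.4 on each, and ranks equal to those of the non-normalized signals. Neither table gives bead numbers or bead standard errors. No genome build is named, so no coordinates are given.

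The main setting started from the non-normalized intensity. In R 4.3.3, the neqc function of limma 3.58.1 corrected the background by normexp, with the mean and SD of the negative controls inferred from the detection p-values, added an offset of 16, quantile normalized the 6 arrays and took log2. A gene entered a comparison when its probe had a detection p-value under 0.01 on at least 1 of the 2 arrays. A gene with several probes was represented by its detected probe with the highest mean over the 6 arrays. Where a gene was detected on 1 array only, the dim array's value was raised to the lowest value among its detected probes, the fold is a bound, and a bound that would turn the direction was set to 0. Such genes enter list medians at their bound. The difference is group minus reference on the log2 scale, and a count takes genes at 2-fold or more. The arrays' number, 1 per group, limits the precision, and no test was run. As a gauge of spread, a probe SD was computed per comparison. It is the SD of the gap between the log2 differences of a gene's 2 brightest probes, divided by the square root of 2. It includes differences between transcripts and is not replicate error.

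Gene names are those of the table, matched to the RefSeq genes of assembly GRCh38.p14. Of 34694 names, 17590 were current symbols, 2181 matched 1 gene through an older symbol and 14923 were kept as in the table. A further check found 27 names that a spreadsheet had turned into dates, which were not named. Y-linked genes, XIST and genes that can be missing from a person's genome, 49 in all, were left out of every result. Small non-coding RNA genes were those annotated as small nuclear, nucleolar or Cajal body RNA, Y, vault, ribonuclease P or MRP, telomerase or 5S ribosomal RNA, or named as 7SK or 7SL. Histone genes were taken by their symbols.

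Named genes were set by a rule before the data were examined. It takes, per comparison and direction, the 10 genes with the largest bounded difference among those with a normalized log2 value of at least 8 on the brighter array and with all other detected probes in the same direction, passing over genes without an established symbol. It adds 2 to 4 members with the largest differences from each list described, and members of the Ras, Myc and IAP list at 2-fold or more. Some genes that meet the rule are not reported here. Lists, 36 in all, were fixed at the same time. A list with at least 5 measured genes was placed among 10000 random lists of the same size matched on mean expression in 10 bins. The percentile describes these arrays and is not a test. Shared genes between comparisons were set beside the number for independent lists and beside 1000 simulations in which all arrays differed by noise as large as the observed differences. These simulations did not keep the sizes of the observed lists and gave the shared array noise drawn from the pooled differences.

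Alternatives were a shift to equal medians, no between-array normalization, quantile normalization of the compared pair, no background correction with values under 16 set to 16, an offset of 50, detection on all 6 arrays, a detection p-value under 0.05, no detection filter, the mean over a gene's probes and the authors' processed values. A further 3 were added after the data were seen. The steps were tested on simulated arrays for blebbishields against live cells, with noise of 0.2 on the log2 scale. There, 10.0% of genes changed 1.5-fold, 46.0% changed 2-fold, 98.0% changed 3-fold and 100.0% changed 4-fold were called at 2-fold, 50 genes at each size among 25884 probes. Of 25684 unchanged probes, 36 were called. The 200 changed genes were drawn only from brighter probes detected on all 6 arrays, with as many raised as lowered. The noise of 0.2 was added to each array, so that of a difference was larger. It was still under the probe SD of 0.40 in the real comparison, which is also of a difference. These rates therefore describe an easier case than the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the counts, lists and plots.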

Results

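RNA levels were measured in 6 samples of RT4, a human bladder cancer cell line, and lines derived from it, with 1 Illumina HumanHT-12 version 4 array per sample. The series asks how the transcriptome differs along the blebbishield emergency program and between lines that differ in tumorigenicity. Blebbishields are structures left after apoptosis that can go on to form transformed spheres. The parental cells, RT4P, were sampled as live cells, as blebbishields after 24 h in 1 uM cisplatin with 20 mM lithium chloride, and as spheres purified after the same treatment and 4 h of transformation. The blebbishield sample held sphere-forming and other blebbishields together. The other 3 samples were untreated live cells. RT4P-BSE2 had passed through the blebbishield program 2 times in series, RT4v6 had been passaged in mice 6 times, and PBSHMS is a fusion line of RT4 blebbishields and human blood mononuclear cells. Each group had 1 array, so no difference has a replicate check, and no p-values are given. Differences describe these 6 arrays, and a gene is called higher or lower when it differed at least 2-fold. Where a gene was not detected on the dimmer array, its fold is a lower bound and is written "at least". A gene counted as under 2-fold can be such a bound. An offset of 16 added to every signal understates the folds of dim genes, and folds depend on the background correction, without which 111 of 120 named gene values moved.

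The RT4P live array detected 16733 of 47322 probes, the sphere array 17593, the RT4P-BSE2 array 17271, the RT4v6 array 16711 and the PBSHMS array 15788. The blebbishield array detected the fewest, 14749, and had a mean signal of 263.2 against 349.5 to 389.2 on the other 5. Across probes, the RT4P live array correlated with that of RT4P-BSE2 at r = 0.984, PBSHMS at 0.975, RT4v6 at 0.973, spheres at 0.963 and blebbishields at 0.939. These correlations are between single arrays, over normalized values of probes detected on at least 1 array, and probes are not replicates.

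**Figure D1:**
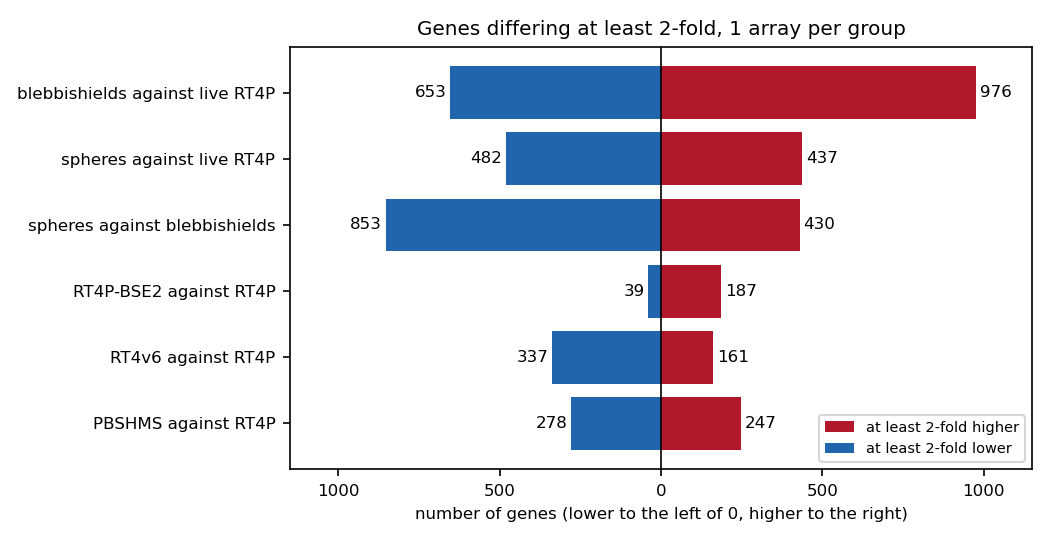
Bars give the number of genes at least 2-fold higher (red, to the right) or lower (blue, to the left) in each of the 6 comparisons, each between 2 single arrays. The blebbishield comparison with live RT4P cells has the most, 976 higher and 653 lower, and RT4P-BSE2 against RT4P the fewest, 187 higher and 39 lower.

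Blebbishields were compared with live RT4P cells to describe the state after cisplatin and lithium. Lists with medians above 0 on the blebbishield array included small non-coding RNAs, histone genes, p53 targets, unfolded protein response and ATF4 targets and immediate early genes, the last at -0.02 without between-array normalization. Interferon-stimulated, MHC class I and basal epithelial genes had medians below 0, and in most of these groups part of the members stayed under 2-fold. Among the largest differences upward were those of the spliceosomal RNA gene RNU4-2 (95.2-fold higher), the small nucleolar RNA SNORD12C (41.4-fold), RPPH1, the RNA component of ribonuclease P (36.5-fold), SNORD13 (27.9-fold), the minor spliceosome gene RNU4ATAC (25.0-fold) and the 5S ribosomal RNA gene RNA5S9 (25.0-fold). Histone genes H4C1 (at least 37.8-fold), H2AC17 (at least 34.8-fold) and HIST1H2BG (at least 33.2-fold) and the AP-1 gene FOSB (at least 28.8-fold) were also among them. Among the largest differences downward were those of the invariant chain gene CD74 (at least 27.1-fold lower), the aldehyde dehydrogenase ALDH7A1 (22.0-fold), the ubiquitin-like UBD (at least 20.2-fold), LPXN (16.4-fold), the matrix metalloproteinase MMP7 (at least 15.9-fold), the protease inhibitor SPINK1 (13.5-fold), IFI6 (12.3-fold), the siderophore-binding LCN2 (log2 difference -3.59) and the lymphotoxin gene LTB (at least 11.5-fold).

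Of 13728 genes measured, 976 were at least 2-fold higher and 653 at least 2-fold lower in blebbishields, and 331 and 83 passed 4-fold. Among small non-coding RNA genes, 88 of 168 were at least 2-fold higher and 0 lower, with a median log2 difference of 1.09 (0.35 without between-array normalization). Histone genes of all kinds gave 25 of 52 higher and 0 lower. Without these 2 classes, a count added after the data were seen, 863 genes were higher and 653 lower. In this comparison, which holds the dimmest array, the probe SD was 0.40 on the log2 scale. For 219 of 254 genes past 2-fold by the brightest probe, a second probe pointed the same way.

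Among lists fixed before the data were examined, p53 target genes had a median log2 difference of 0.93 in blebbishields (0.13 without between-array normalization), above all 10000 random lists matched on expression. Of 23 measured, 9 were at least 2-fold higher, 0 lower and 14 under 2-fold. GDF15 was 6.04-fold higher, ZMAT3 5.03-fold, and MDM2, the ubiquitin ligase that targets p53, 4.35-fold. The unfolded protein response and ATF4 list stood at 0.84 (0.21 without between-array normalization), with 9 of 22 higher, 1 lower and 12 under 2-fold, including the transcription factor DDIT3 (5.47-fold), the serine synthesis gene PSAT1 (3.18-fold) and CHAC1 (at least 3.00-fold). Immediate early genes stood at 0.69 (-0.02 without between-array normalization), with 8 of 18 higher, 0 lower and 10 under 2-fold. FOS was 10.5-fold higher, EGR1 9.62-fold and KLF4 4.01-fold. Replication-dependent histones stood at 1.03 (0.20 without between-array normalization and 0.34 over genes detected on all 6 arrays), with 9 of 16 higher and 0 lower. The stem cell list stood at 0.73 (-0.01 without between-array normalization and 0.20 without a detection filter), and its members split, with 4 of 12 higher, 2 lower and 6 under 2-fold. ALDH1A1 was at least 10.5-fold higher and SALL4 4.05-fold higher, while the receptor gene KIT was 4.97-fold lower. NRF2 targets stood at 0.48 (-0.32 without between-array normalization), with 3 of 18 higher, among them OSGIN1 at 2.64-fold and HMOX1 at 2.24-fold.

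Interferon-stimulated genes had a median of -1.43 in blebbishields, with 20 of 28 at least 2-fold lower, 0 higher and 8 under 2-fold. Only 14 of the 28 were detected on the blebbishield array, so part of these values are bounds. The 8 include BST2, whose log2 value was 6.01 in live cells and 4.59, undetected, in blebbishields. IFIT1 was at least 8.80-fold lower, the antiviral GTPase gene MX1 7.88-fold and OAS2 6.09-fold. MHC class I and antigen processing genes stood at -0.83, with 4 of 11 lower and 0 higher, HLA-B at 2.93-fold and PSMB9 at least 2.91-fold. Basal and squamous genes stood at -0.88 (-0.15 without a detection filter), with 6 of 12 lower and 0 higher, including SPRR3 (8.97-fold), KRT16 (4.61-fold), KRT17 (3.63-fold) and the basal transcription factor TP63 (3.23-fold). G2/M cell cycle genes stood at -0.58, with 5 of 28 lower, 0 higher and 23 under 2-fold, KIF20A at 5.79-fold and CCNB1 at 2.67-fold. NF-kB targets and cytokines stood at -0.52 (-0.20 without a detection filter), with 3 of 14 lower and 1 higher. The chemokine genes CCL20 and CXCL1 were 5.45-fold and 3.22-fold lower, and BIRC3, an inhibitor of apoptosis, was 2.99-fold higher. S100 and secreted inflammation genes stood at -0.44, with 5 of 14 lower and 2 higher, S100A9 at 9.71-fold lower and S100A14 at 5.38-fold higher. Cytosolic ribosomal protein genes stood at -0.35 (-0.11 with arrays shifted to equal medians), with 1 of 32 lower and 0 higher. BCL2 family and caspase genes had a median of 0.00, with 4 of 23 lower, among them CASP1 (at least 5.03-fold) and BID (2.87-fold), and Wnt targets, read as lithium inhibits the kinase GSK3, had a median of 0.00 with 1 of 11 higher and 1 lower. Without between-array normalization the median of all genes on this comparison was -0.77, so the list medians above are relative to the typical gene, and the split of 59.9% higher among 2-fold genes became 9.3%, or 72.8% when arrays were only shifted to equal medians.

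Spheres were compared with live RT4P cells to describe the state reached after transformation. NRF2 targets had a median above 0 on the sphere array, and interferon-stimulated, G2/M, cholesterol synthesis and NF-kB target genes had medians below 0, with part of each group under 2-fold. CYP1A1, a cytochrome P450 of xenobiotic metabolism, was at least 161-fold higher, the retinaldehyde dehydrogenase ALDH1A1 at least 31.2-fold, the retinol dehydrogenase DHRS9 27.1-fold, the secreted phosphoprotein SPP1 24.5-fold, ALDH3A1 23.1-fold and HMOX1, heme oxygenase 1, 17.6-fold. AADAC (17.1-fold), CEACAM6 (at least 14.4-fold), CYP4F3 (14.1-fold) and AGPAT9 (13.1-fold) followed. CD74 was 28.7-fold lower, SNCAIP at least 22.7-fold, UBD 20.8-fold, ALDH7A1 19.7-fold, LTB at least 15.9-fold and the aspartic protease CTSE at least 14.8-fold. IFIT1 (at least 12.1-fold), IFI6 (11.2-fold), CCL20 (10.8-fold) and IFI27 (at least 9.27-fold) were also lower.

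Of 14552 genes measured, 437 were at least 2-fold higher and 482 at least 2-fold lower in spheres, 74 and 81 of them by 4-fold. Small non-coding RNA genes gave 24 of 137 higher and 1 lower, with a median of 0.20. The probe SD was 0.26, and a second probe pointed the same way for 149 of 152 genes.

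NRF2 target genes, which respond to oxidative and electrophilic stress, had a median log2 difference of 1.62 in spheres, with 13 of 18 at least 2-fold higher, 0 lower and 5 under 2-fold. AKR1B10 was 7.42-fold higher, the cystine transporter SLC7A11 at least 7.13-fold and the thioredoxin reductase TXNRD1 4.34-fold. Metallothioneins stood at 1.36 (0.02 without a detection filter), with 3 of 5 higher, MT1X at 5.83-fold and MT2A at 2.77-fold. The stem cell list stood at 0.32 (0.04 without a detection filter), with 3 of 14 higher and 1 lower, including ALDH1A3 (10.3-fold higher), KLF4 (8.29-fold higher) and KIT (4.39-fold lower). The p53 targets stood at 0.27, with 4 of 23 higher and 0 lower, GDF15 at 3.82-fold and MDM2 at 2.24-fold. Replication-dependent histones stood at 0.37 (0.19 to 0.48 across settings), with 4 of 16 higher.

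Interferon-stimulated genes stood at -1.17 in spheres, with 15 of 28 lower, 0 higher and 13 under 2-fold, IFI44 at 6.91-fold. G2/M genes stood at -1.02, with 14 of 28 lower and 0 higher, while G1/S genes had a median of 0.10 with 0 of 27 past 2-fold. The G2/M members included KIF20A (9.25-fold), CENPA, the centromeric histone (6.26-fold), and HMMR (5.60-fold). Cholesterol synthesis genes stood at -0.87, with 9 of 20 lower and 0 higher. HMGCS1, a synthase early in the pathway, was 3.39-fold lower and INSIG1 3.35-fold. NF-kB targets and cytokines stood at -0.86 (-0.33 without a detection filter), with 6 of 13 lower and 0 higher, CXCL1 at 8.12-fold, IL1A at 4.91-fold and IL1B at 3.43-fold. Pan-leukocyte and monocyte markers stood at -0.71 over 6 genes (-0.27 without a detection filter) and -0.57 over 7 genes, with HCLS1 6.90-fold and S100A8 8.93-fold lower. For the monocyte markers the median was 0.05 without a detection filter. Among luminal genes, whose median was 0.03, the keratin gene KRT20 was 12.1-fold higher and the receptor gene FGFR3 3.17-fold lower.

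Spheres were compared with blebbishields to describe what differed between the 2 post-apoptotic samples. CYP1A1 was at least 125-fold higher in spheres, the small GTPase ARL14 by a log2 difference of 4.00, LCN2 13.7-fold, MALL 13.2-fold, EMP1 by a log2 difference of 3.59, the hyaluronan-binding CEMIP at least 9.65-fold, ALDH3A1 9.49-fold, HMOX1 7.87-fold, FEZ1 7.68-fold and the cornified envelope gene SPRR1A 7.67-fold. The immediate early genes FOS (21.6-fold lower), FOSB (19.2-fold) and EGR1 (11.4-fold) were among the largest differences downward, with the histone genes H2AC17 (15.9-fold), H4C1 (14.2-fold), HIST1H2BG (14.1-fold) and H2BC3 (12.7-fold) and the small RNAs RNU12 (12.7-fold), RNU4ATAC (12.4-fold) and SNORD12C (12.2-fold).

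Of 14182 genes measured, 430 were at least 2-fold higher and 853 at least 2-fold lower in spheres than in blebbishields, 43 and 134 of them by 4-fold. Small non-coding RNA genes gave 94 of 176 lower and 0 higher, and histone genes 23 of 51 lower. Without these 2 classes the counts were 430 and 736. The probe SD was 0.34, and a second probe pointed the same way for 184 of 217 genes. The median of all genes was 0.83 without between-array normalization, where 95.8% of 2-fold genes were higher in place of 33.5%, and 18.7% were higher with arrays shifted to equal medians.

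Metallothioneins had a median log2 difference of 2.07 between spheres and blebbishields (0.07 without a detection filter), with 4 of 5 higher, MT1A at 5.59-fold and MT2A at least 4.21-fold. NRF2 targets stood at 1.10, with 11 of 18 higher and 0 lower, AKR1B10 at 7.28-fold and SLC7A11 at 4.05-fold. Basal and squamous genes stood at 0.67 (0.04 without a detection filter), with 4 of 12 higher, SPRR3 at 6.83-fold and the hyaluronan receptor CD44 at 3.23-fold. MHC class I genes stood at 0.60 with 0 of 11 past 2-fold. Interferon-stimulated genes stood at 0.43 (0.18 to 1.13 across settings) with 3 of 23 higher, among them ISG20 (at least 3.23-fold) and MX1 (3.16-fold). In this list 14 genes were detected in blebbishields and 23 in spheres. Genes detected only in spheres entered at 0 or above by the bound, which favours a median above 0. The Ras, Myc and IAP list stood at 0.30, with the caspase inhibitor XIAP at least 2.07-fold higher and BIRC3 2.89-fold lower.

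Several lists had medians below 0 in spheres against blebbishields relative to the typical gene. Part of each list stayed under 2-fold, such as 25 of 28 G2/M genes and 19 of 23 p53 targets. These medians were above or at 0 without between-array normalization, as given first in parentheses, where the median of all genes was 0.83. The NF-kB and cytokine list stood at -0.86 (0.00 without between-array normalization and -0.11 without a detection filter), with 6 of 14 lower and 1 higher, IL1A at 3.30-fold lower and SOD2 at 3.07-fold higher. Cholesterol genes stood at -0.72 (0.15), with 6 of 20 lower, MVK at 2.81-fold. G2/M genes stood at -0.68 (0.22), with 3 of 28 lower, CENPA at 3.32-fold and DLGAP5 at 2.70-fold. The p53 targets stood at -0.66 (0.17), with 4 of 23 lower, SESN2 at 3.30-fold and ZMAT3 at 2.59-fold. Replication-dependent histones stood at -0.47 (0.26), with 6 of 17 lower and H2AC8 at 9.19-fold. The unfolded protein response and ATF4 list stood at -0.42 (0.33), with 8 of 22 lower and 2 higher, DDIT3 at 7.43-fold and the mTORC1 inhibitor DDIT4 at 6.36-fold lower. Immediate early genes stood at -0.29 (0.46), with 8 of 19 lower and 1 higher, DUSP1 at 6.57-fold and ATF3 at least 4.76-fold lower. The hypoxia and glycolysis list stood at -0.19 (0.71), with 3 of 23 lower and 1 higher, ANKRD37 at least 3.12-fold lower and EGLN3 3.44-fold higher.

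Blebbishields and spheres shared 173 genes higher and 259 lower than live RT4P cells among 13338 genes measured in both. Independent lists of these sizes would share 27.1 and 23.6. Both comparisons use the same RT4P live array, and a simulation in which every observed difference was noise around that shared array gave a mean of 252 in each direction, with ranges of 221 to 283 higher and 222 to 283 lower. The 259 lower genes lie inside that range and the 173 higher genes below it. The simulation overstates noise in the live array. RT4P-BSE2 differed from that array with an SD of 0.41, against 0.84 for blebbishields and 0.62 for spheres. Noise in the live array would also recur in the derived lines. Yet of 13083 genes measured in all 5 comparisons with it, 0 were higher and 1 lower in each. This argues against errors of 2-fold or more in the live array alone as the source of the overlap, for those genes. Smaller errors there, added to differences on the blebbishield and sphere arrays, are not excluded, since few genes passed 2-fold in RT4P-BSE2. The shared genes were not examined as a set in the derived lines. The shared genes included ALDH1A1, KRT20 and the amino acid transporter SLC7A5 upward and CD74, UBD, ALDH7A1, LTB and IFI6 downward, named here after their values were seen. The overlap cannot be checked with a split reference, since there was 1 reference array.

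RT4P-BSE2 was compared with RT4P to describe cells that had passed through the program. Of interferon-stimulated genes 26 of 28 were higher, and of hypoxia and glycolysis genes 8 of 25, and few genes were lower. The hypoxia-inducible carbonic anhydrase CA9 was at least 23.2-fold higher, the interferon-induced IFITM1 16.6-fold, IFI44L 11.9-fold, the tethering factor BST2 11.9-fold, IFI27 11.9-fold, the chemokine CXCL10 10.3-fold, the collagen lysyl hydroxylase PLOD2 9.96-fold, IFIT1 9.81-fold, MX2 9.52-fold and the ubiquitin-like ISG15 by a log2 difference of 3.00. Among genes bright enough to be named by the fixed rule, differences downward were small, from ANXA3 (2.91-fold), MALL (2.82-fold), the Wnt inhibitor DKK1 (2.52-fold), JUN (2.49-fold) and ADAMTS1 (2.32-fold) to EDN1 (2.10-fold), KRT18 (2.10-fold), RHOBTB3 (2.05-fold), JPH1 (2.04-fold) and PALLD (2.00-fold), while the dimmer TAGLN was at least 6.00-fold lower.

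Of 14273 genes measured, 187 were at least 2-fold higher and 39 at least 2-fold lower in RT4P-BSE2, 40 and 2 of them by 4-fold, with a probe SD of 0.22 and a second probe in the same direction for 45 of 45 genes. The share of 2-fold genes that were higher was 82.7%, and 95.2% without background correction, where only 5 genes were lower. Interferon-stimulated genes had a median log2 difference of 2.12, with 26 of 28 at least 2-fold higher, 0 lower and 2 under 2-fold. MHC class I genes stood at 0.50, with 3 of 12 higher, HLA-B at 2.56-fold and the peptide transporter genes TAP2 and TAP1 at 2.32-fold and 2.04-fold. The hypoxia and glycolysis list stood at 0.62, with 8 of 25 higher and 0 lower, including BNIP3 (4.26-fold), ALDOC (4.26-fold), NDRG1 (3.68-fold) and ENO2 (3.67-fold). Luminal genes stood at 0.17, with 5 of 22 higher and 1 lower, KRT20 at 4.72-fold and the uroplakins UPK2 at 3.16-fold and UPK1A at 2.94-fold. Metallothioneins stood at 0.59 (0.14 without a detection filter), with 2 of 5 higher, MT1A at 2.88-fold and MT2A at 2.74-fold, and the stem cell list at 0.28 (0.10 without a detection filter), with 2 of 12 higher, KLF4 at 2.82-fold and KIT at 2.30-fold. Lists outside the central 95% of random lists but with no member past 2-fold were G1/S and replication genes at -0.42 over 26 genes, NRF2 targets at -0.28 over 17, cholesterol genes at -0.16 over 20, G2/M genes at 0.29 over 28, p53 targets at 0.17 over 24 and NF-kB targets at 0.15 over 14. Across settings the p53 median fell as low as 0.08 and the NF-kB median as low as 0.05. Replication-dependent histones stood at 0.29 (0.14 at the lowest across settings) with 1 of 15 higher. S100 and secreted inflammation genes stood at 0.26 with SAA1 2.37-fold higher and the protease inhibitor SLPI 2.35-fold lower, a median that was -0.05 over genes detected on all 6 arrays.

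RT4v6 was compared with RT4P to describe cells passaged in mice. The cancer-testis antigen genes XAGE1A (at least 20.8-fold) and XAGE1 (at least 20.1-fold), near-identical copies that the probes may not separate, were higher, as were BST2 (18.3-fold), CEMIP (7.96-fold), ALG1L1P (at least 7.73-fold), the prostate stem cell antigen PSCA (6.73-fold), MYRIP (6.71-fold), CXCL10 (6.05-fold), ABCA6 (4.54-fold) and the growth factor binding protein gene IGFBP4 (4.48-fold). IGFBP5 was 32.3-fold lower, SPINK1 23.6-fold, the D-type cyclin CCND2 22.8-fold, SNCAIP at least 21.1-fold, the actin-binding CALD1 20.6-fold, SPRR3 12.4-fold, UBD 12.2-fold, MMP7 11.2-fold, ANXA3 at least 9.32-fold and DPYSL3 at least 8.78-fold.

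Of 14063 genes measured, 161 were at least 2-fold higher and 337 at least 2-fold lower in RT4v6, 16 and 64 of them by 4-fold, with a probe SD of 0.25 and a second probe in the same direction for 64 of 66 genes. Only 4 lists lay outside the central 95% of random lists. S100 and secreted inflammation genes stood at -0.33, with 3 of 14 lower and 0 higher, S100A8 at 3.88-fold, SLPI at least 3.02-fold and LCN2 at 2.64-fold. MHC class II genes stood at -0.56 over 5 genes and monocyte markers at -0.41 over 6 (-0.05 and -0.02 without a detection filter). Interferon-stimulated genes stood at -0.19 (-0.20 to -0.06 across settings) and split. Of 28, 2 were higher, the already named BST2 and CXCL10, and 4 lower, including IFI44L (at least 3.56-fold) and MX1 (2.40-fold). Luminal genes had a median of 0.02, with 4 of 22 higher and 0 lower, among them KRT20 (3.49-fold) and UPK2 (3.33-fold). Stroma markers were members only, and both measured genes, TAGLN (at least 5.71-fold) and ACTA2 (2.65-fold), were lower.

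PBSHMS was compared with RT4P to describe the fusion line. The cadherin gene CDH2 was 18.0-fold higher, the proteoglycan gene SPOCK1 12.4-fold, the metalloproteinase inhibitor TIMP3 11.4-fold, the myosin kinase MYLK 9.77-fold, CPA4 at least 9.60-fold, the sodium channel gene SCN9A 9.33-fold, the smooth muscle genes TAGLN 8.32-fold and ACTG2 6.88-fold, PRRG1 at least 7.81-fold and IGFBP5 6.71-fold. CD74 was 29.3-fold lower, FCGBP 22.7-fold, HOXD1 14.1-fold, MMP7 12.6-fold, LCN2 10.5-fold, SNCAIP 10.4-fold, CXCL10 at least 9.14-fold, S100A8 at least 8.04-fold, AUTS2 7.79-fold and IFI27 at least 7.79-fold.

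Of 13660 genes measured, 247 were at least 2-fold higher and 278 at least 2-fold lower in PBSHMS, 25 and 35 of them by 4-fold, with a probe SD of 0.24 and a second probe in the same direction for 92 of 94 genes. Interferon-stimulated genes stood at -1.07 (-0.71 without background correction), with 16 of 28 lower, 0 higher and 12 under 2-fold, IFI6 at 5.54-fold and MX1 at 5.53-fold. Both measured stroma markers were higher, TAGLN as above and ACTA2 at 3.11-fold. Besides CD74, the MHC class II genes HLA-DMB (at least 3.09-fold) and HLA-DMA (2.18-fold) were lower. Luminal genes stood at 0.43, with 5 of 22 higher and 0 lower, UPK2 at 3.70-fold, UPK1A at 3.17-fold and UPK3A at 2.49-fold. The p53 targets stood at 0.60, with 4 of 23 higher and 0 lower, SPATA18 at least 4.22-fold and RRM2B at 2.56-fold. Immediate early genes stood at 0.42, with 4 of 18 higher and 1 lower, CCN1 at 2.65-fold higher and FOS at 3.03-fold lower. Wnt targets stood at 0.33 (-0.14 over genes detected on all 6 arrays), with 2 of 11 higher and 2 lower, DKK1 at 4.37-fold higher and ASCL2 at 2.68-fold lower. NF-kB targets stood at -0.35 (-0.07 without a detection filter), with 4 of 14 lower and 1 higher, CCL20 at 3.83-fold and CXCL8 at 2.87-fold lower. Cholesterol genes stood at -0.40, with 3 of 20 lower, INSIG1 at 2.27-fold and HMGCS1 at 2.13-fold. Metallothioneins stood at -0.69 (-0.29 without background correction), with 1 of 5 lower, MT1A at least 2.64-fold, and the hypoxia list at -0.20, with 3 of 23 lower, NDRG1 at 2.76-fold. Replication-dependent histones stood at 0.28 with 4 of 13 higher, heat shock genes at 0.20 (0.03 without between-array normalization) with 1 of 14 higher, epithelial junction genes at 0.27 (0.11 without it) with 0 of 18 past 2-fold and G1/S genes at -0.21 with 0 of 26. Of 68 blood cell markers on the array, 7 were detected in PBSHMS and 14 in RT4P live cells.

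The 3 derived lines shared 6 genes at least 2-fold higher than RT4P among 13188 genes measured in all, against 0.0314 for independent lists and 51.9 in the simulation in which every difference was noise around the shared array. The 6 were the uroplakins UPK2 and UPK1A, RAP1GAP2, the carbonic anhydrase CA2, FAM234B and PSCA. The 4 shared genes that were lower, against 0.0210 and 51.9, were CYP3A7, SLPI and 2 loci without an established name. The simulation did not keep the sizes of the lists, and its mean exceeds the 39 genes lower in RT4P-BSE2. It is therefore no benchmark for these shared counts. The numbers for independent lists are no benchmark either, since the 3 comparisons share the RT4P live array. These genes were picked by the overlap itself, after their values were seen. Across all 5 arrays set against RT4P live, 1 gene was lower in each and 0 were higher in each. That gene is a locus among the 4 shared lower genes. For it, a high value on the RT4P live array cannot be told apart from a difference in the derived lines.

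**Figure D2:**
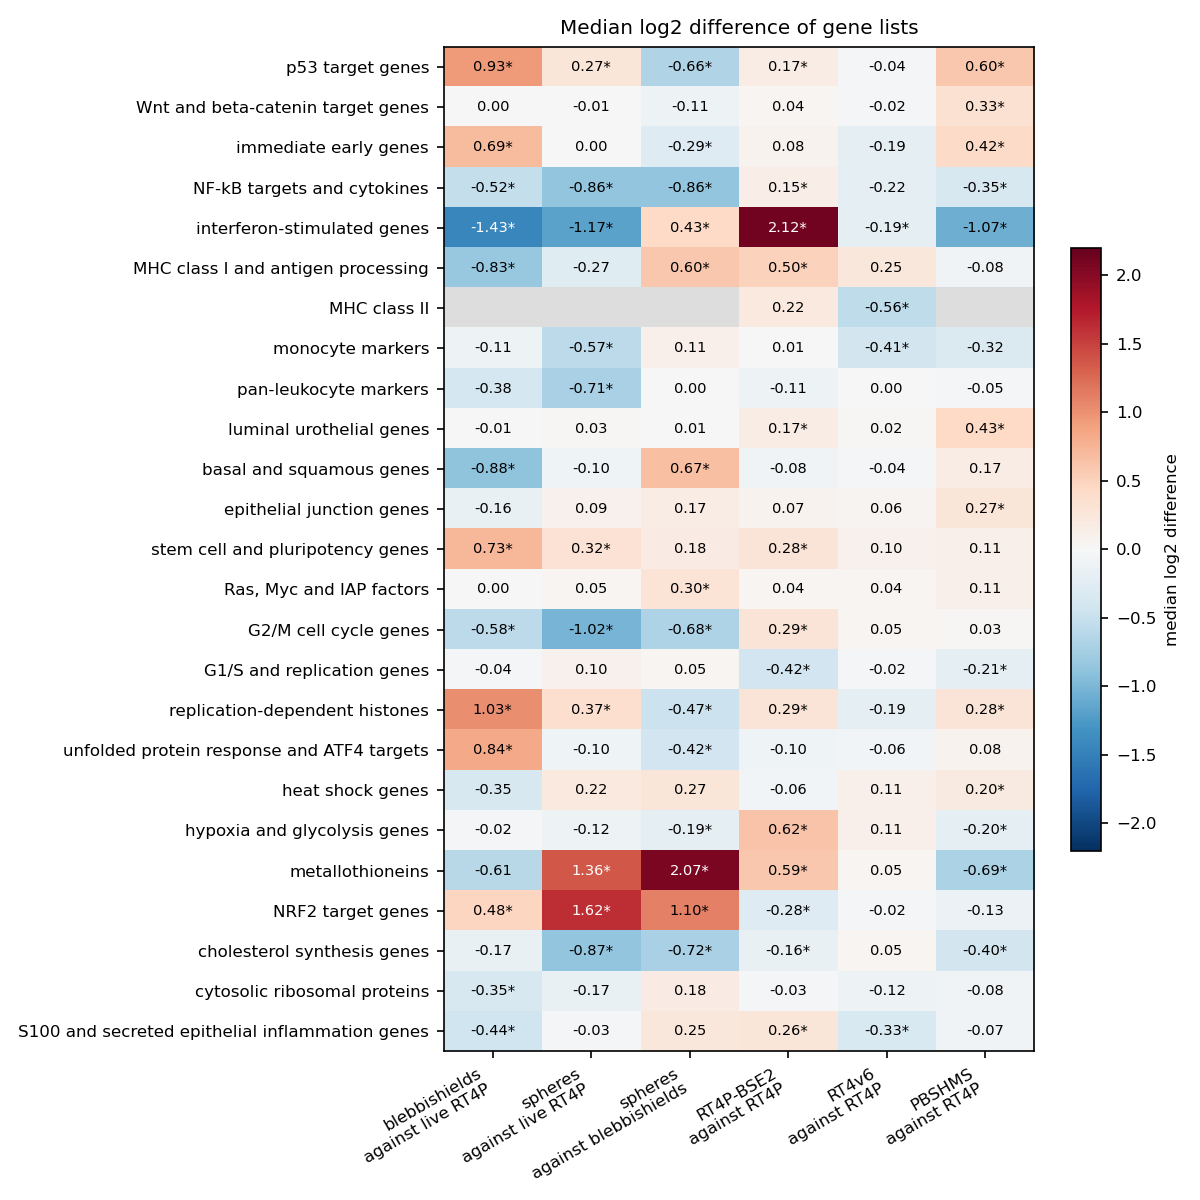
Cells give the median log2 difference of each gene list (lines) in each comparison (columns), with red for higher and blue for lower, for lists outside the central 95% of random lists in at least 1 comparison. A star marks such a median, grey marks fewer than 5 measured genes, and medians range from -1.43 for interferon-stimulated genes in blebbishields to 2.12 in RT4P-BSE2. Without between-array normalization 3 starred medians of blebbishields against live cells and 8 of spheres against blebbishields were at 0 or on its other side.

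**Figure D3:**
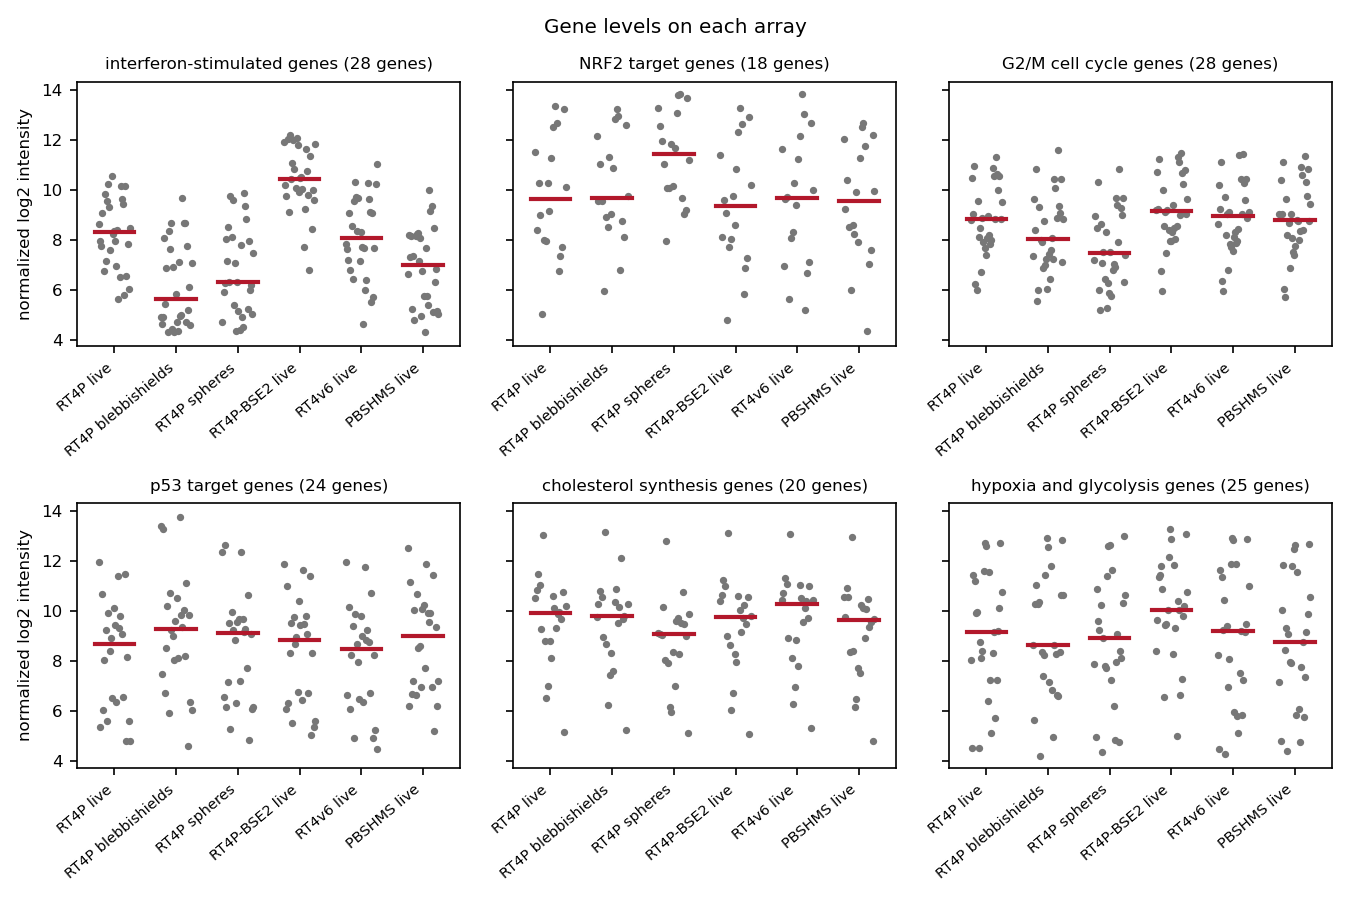
Points are the normalized log2 intensities of the genes of 6 lists on each of the 6 arrays, and red lines are medians over genes detected on at least 1 array. These values are without bounds for undetected genes, so gaps between them can exceed the list median differences in the text. The interferon-stimulated median was 8.29 on the RT4P live array, 5.64 for blebbishields, 6.30 for spheres and 10.44 for RT4P-BSE2, and the NRF2 target median was 11.44 for spheres against 9.63 for RT4P live.

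Across the 36 lists, 69 of 182 medians with a percentile lay outside the central 95%, where 9.1 would if list members varied like random genes. Members of a list may vary together. The medians are also not independent, since lists share genes and 5 comparisons share the RT4P live array. So 1 odd array can place a list outside in several comparisons. ERK feedback genes, BCL2 family and caspases, mesenchymal genes, lysosome and autophagy genes, oxidative phosphorylation genes and housekeeping genes lay inside it in all 6 comparisons. Their single members still differed, as with EMP1 (11.7-fold higher in spheres than in live cells) and SNAI2, an epithelial-mesenchymal transition factor (9.15-fold lower there).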

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

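Of the settings here, no bound for undetected genes, normalization without the blebbishield array, and no small RNA or histone genes were chosen after the data were seen. With 1 array per group, leaving out a replicate was not possible. Where no construction is named, the cause was not tested.

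Without between-array normalization, blebbishields against live cells gave 428 genes higher and 4194 lower, and spheres against blebbishields 4631 and 205, since the medians of all genes were then -0.77 and 0.83. The medians of 3 lists in the first comparison turned, NRF2 targets to -0.32, immediate early genes to -0.02 and the stem cell list to -0.01. In the second, G2/M genes turned to 0.22, NF-kB targets to 0.00, cholesterol genes to 0.15, the hypoxia list to 0.71, immediate early genes to 0.46, p53 targets to 0.17, replication-dependent histones to 0.26 and the unfolded protein response list to 0.33. With arrays shifted to equal medians the counts were 1277 and 476 for blebbishields against live cells and 290 and 1260 for spheres against blebbishields.

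Without background correction, which leaves the background in both values and so shrinks folds, counts were 541 higher and 273 lower for blebbishields against live cells, 174 and 203 for spheres against live cells, 150 and 424 for spheres against blebbishields, 99 and 5 for RT4P-BSE2, 48 and 116 for RT4v6 and 77 and 94 for PBSHMS. The derived lines then shared 2 higher and 1 lower, and blebbishields and spheres 64 and 120. The authors' processed values, which also keep the background, gave 548 and 278, 179 and 207, 159 and 432, 100 and 5, 51 and 127, and 82 and 103 in the same order, with 2 and 1 shared by the derived lines and 63 and 120 by blebbishields and spheres.

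An offset of 50, which shrinks the folds of dim genes by construction, gave 413 lower for blebbishields against live cells, 259 higher and 292 lower for spheres against live cells, 246 and 558 for spheres against blebbishields, 9 lower for RT4P-BSE2, 74 and 193 for RT4v6 and 126 and 160 for PBSHMS. The derived lines shared 2 higher and 1 lower, and blebbishields and spheres 94 higher.

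With only genes detected on all 6 arrays, which removes every bound, 283 genes were higher in spheres than in live cells, with 101 and 22 for RT4P-BSE2, 100 and 212 for RT4v6 and 162 and 181 for PBSHMS. The derived lines shared 1 lower, and blebbishields and spheres 168 lower. The S100 list in RT4P-BSE2 turned to -0.05 and Wnt targets in PBSHMS to -0.14. Without a detection filter, monocyte markers in spheres against live cells turned to 0.05 and Wnt targets in PBSHMS to -0.02.

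Without a bound for undetected genes, 686 genes were higher in spheres than in blebbishields, 69 lower in RT4P-BSE2 and 12 lower in all derived lines. Normalized without the blebbishield array, the counts were 451 and 498 for spheres against live cells, 193 and 44 for RT4P-BSE2, 172 and 352 for RT4v6 and 261 and 290 for PBSHMS. Without small RNA and histone genes, spheres against live cells gave 406 and 480. Without a detection filter, which brings undetected genes into the lists, metallothioneins stood near 0, at 0.02 in spheres against live cells, 0.07 in spheres against blebbishields and 0.14 in RT4P-BSE2. Basal and squamous genes stood at 0.04 in spheres against blebbishields. Monocyte markers in RT4v6 stood at -0.02, with detection p under 0.05 too. Over all settings, 719 list medians kept their direction and size, 59 moved in size and 15 turned or reached 0. Of named gene values, 921 kept their size, 414 moved and 0 turned. The moves were concentrated, with 111 of 120 values without background correction, 110 with the authors' processed values and 92 with an offset of 50.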

Other observations

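The tests of ribosomal protein genes, of small RNAs relative to all genes and to genes of the same live level, of abundant leukocyte transcripts in RT4P-BSE2, of blood markers in PBSHMS and of receptor targets detected in live cells were chosen after the results they bear on were seen, those of small RNAs, leukocyte transcripts and receptor targets because earlier tests decided nothing.

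IL7R, the interleukin 7 receptor gene, was 11.4-fold higher in spheres than in live RT4P cells and 7.32-fold higher than in blebbishields, while the other T and NK cell markers measured stayed under 2-fold. LCP1, an actin-bundling protein, was 8.62-fold lower in RT4v6 than in RT4P. These genes were chosen after their values were seen.

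The median of small non-coding RNA genes was higher in blebbishields than in live RT4P cells. Normalization of a dim array was first tested by their median without between-array normalization, 0.35, between the bounds of 0.3 and 1 set beforehand, and then by its distance from the median of all genes, 1.12, which decides nothing, as many of these genes were detected on the blebbishield array only. Among 108 small RNA genes detected on the live array, the median lay 1.19 above that of other genes at the same live level, with 101 above it, which speaks against normalization as the whole cause. Better recovery of every short RNA would raise ribosomal protein messages, and their median was -0.35, and from -0.97 to -0.11 over the other settings. These are messenger RNAs, so they cannot decide whether small non-coding RNAs were better recovered, and that stays open. Histone genes, with 25 of 52 higher and 0 lower, rose too, so the rise was not confined to small non-coding RNAs. A cause common to both classes was not tested. Nuclear RNA kept while cytoplasmic RNA was lost cannot be told apart from the treatment, since nuclear long non-coding RNAs had a median of 0.00 over only 3 genes. That 0.00 is a bound, for KCNQ1OT1, with TUG1 at 0.04 and SNHG5 at -0.71. The rule for this test was made stricter after the median was seen, and a biological difference also stays open.

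Interferon-stimulated genes were higher in RT4P-BSE2 than in RT4P. Their median was 2.11 without between-array normalization, against 2.12 with it, which speaks against normalization as the cause. Leukocytes among the cells were first tested by blood markers, of which 1 more was detected than in RT4P, a value between the bounds set beforehand that left this open. A later test found 0 of 8 abundant leukocyte transcripts, including PTPRC, CD52 and LYZ, detected on the RT4P-BSE2 array. This speaks against such cells for those 8 transcripts only. CD52 and CORO1A lay near the cut there, at a detection p-value of 0.017 each. Outside the 8, CD14 was detected there (detection p-value 0.009) and not in RT4P live, and CD79A was detected in both. A lasting response in cells that survived the program may be the source and was not tested further, and culture conditions on the day of sampling were not compared.

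A hypothesis for the high CYP1A1 and ALDH3A1 in spheres is that aryl hydrocarbon receptor targets were raised as a group. The 7 measured genes of a list of other targets, written before their values were seen, had a median log2 difference of 1.18, with quartiles of 0.27 and 1.94. CYP1A2 was at least 5.87-fold higher, CYP1B1 at least 4.85-fold, SCIN at least 3.02-fold and UGT1A6 2.27-fold, while TIPARP stood at a log2 difference of 0.38, AHR at 0.17 and NFE2L2 at 0.01. Genes such as CYP1A2 entered only by being detected in spheres, so this median decides nothing. The 4 target genes detected on the live array had a median of 0.27, between the bounds of 0 and 0.5, and the hypothesis stays open. A second hypothesis was that a fusion line with blood mononuclear cells holds blood cell marker transcripts. The number detected differed by -7 from RT4P live cells, with 0 gained, which speaks against it for these 68 markers. The size of the loss is less sure. The PBSHMS array detected fewer probes in all, 15788 against 16733. CD79A crossed the cut narrowly, with a detection p-value of 0.008 in RT4P live and 0.013 in PBSHMS.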
